A study of Homo sapiens with 96 samples.

How the data were processed

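The data were 96 deposited tables of gene counts, 1 per well of a plate with 8 rows and 12 columns, from RNA of single HUES64 cells at day 0. Per the labels, messenger RNA was captured by its poly(A) tail, separated from the genomic DNA, amplified by SMART-seq2 and made into libraries with Nextera XT. Per the submitters' processing notes, the authors used FastQC, STAR 2.7.3a and the builds GRCh38.p2 and hg38; the annotation release, trimming and duplicate removal are not given in the sources used here. Each table the authors deposited held raw counts of reads per gene for 58521 gene symbols in 3 columns, without regard to strand and for each strand, under 4 summary lines. No molecular identifiers and no spike-in were present. Of all reads, 88.8% stood in the summary lines (unmapped, mapped to more than 1 place, outside genes, ambiguous), and these entered only as shares. The column without regard to strand was used.

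All wells carried the same labels and formed 1 group, so no test between conditions and no paired analysis was made. The well was taken from the title. For 16 wells in columns 1 and 12 the name of the table gave the other of these columns, and the titles were followed. Gene lists, quality thresholds, tests, relations and the first set of alternative settings were fixed before the data were examined. A library passed with at least 100000 gene reads and 2000 genes with a read. Levels were CPM, the reads of a gene scaled to a common total of gene reads. Genes were placed on GRCh38 with GENCODE 29, which matched 36084 of the 58521 symbols; it is not known to be the annotation the authors used.

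Genes with at least 1 read were counted as detected, also after thinning to 100000 gene reads (seed 1) and in pools of 10 cells (100 draws). Correlation between cells used genes with a read in at least 10% of passing libraries. Shares of libraries have exact Clopper-Pearson 95% intervals. Variability was the excess of log2 CV2 over a loess trend (span 0.5) on log2 mean CPM, for genes with a mean of at least 10 CPM and a read in at least 10% of libraries. Lists with at least 5 such members were set against 10000 random lists matched on mean level. Scores were means of z-scored log2(CPM + 1). Relations and plate position were tested by two-sided permutation with 100000 resamples. Single genes with a read in at least 50% of passing libraries were tested for plate row and plate column in 1 model by edgeR's quasi-likelihood test with TMM factors. Benjamini-Hochberg adjustment and a threshold of 0.05 were used throughout.

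The edgeR test used the dispersion trend of estimateDisp, estimated on every 5th gene in order of abundance. This was decided after results with glmQLFit's default dispersion had been seen, because that default called 226 of 12156 unchanged genes by row and 724 of 12356 by column when tested on simulated data. With the trend, 9 unchanged genes were called by row and 9 by column, and 13 of 100 genes with a 4-fold change and 63 of 100 with a 16-fold change were recovered. limma-trend called 6 unchanged genes by row and 0 by column, and recovered 6 and 42 of 100. Each simulated gene varied independently of the others, so these rates need not hold for the real counts. There edgeR called 337 to 730 genes over regrouped columns (median 464) and 0 to 27 over regrouped rows (median 8.5). Calls by column with edgeR thus hold many that regrouping alone gives. In simulated libraries the variability threshold called 85 of 100 genes with 4 times the variance of the trend, 88 of 100 with 8 times and 125 of 9072 on it. A list sharing a factor stood at the 100 percentile of co-variation and one sharing none at 24.3. Unrelated pairs gave a p under 0.05 in 11 of 400 cases and pairs with a true r of 0.4 in 390 of 400. Measures with no row effect gave 27 of 400.

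The genes named are DNMT1, the 10 with the highest mean CPM apart from mitochondrially encoded ones, the 25 with the largest excess variability, up to 4 members of each list with the highest mean, list members past the variability threshold and the genes in the relations. Other names, among them NANOG, SOX2, ZFP42, KLF17, DPPA3, DPPA5, POU5F1, PDGFRA, SOX1, GAPDH, CCNA2, the mitochondrial genes and the genes of well D4, were chosen after their values were seen. Alternatives covered the thresholds, strand column, pseudocount, depth, scaling (scran), filters, parts of the plate and tools (limma-trend, DESeq2). Further ones, such as leaving out rows F and G or libraries under 1% mitochondrial reads, were added after the data were seen.

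The median library had 660168 gene reads, from 768 to 1877837, and a passing library had a floor of 1.60 to 28.4 CPM for 3 reads. The 6 libraries that did not pass were left out of levels and of the 15 relations; 3 of them, with more than 10000 gene reads, entered the pool of libraries with under 1% mitochondrial reads and the relations of KCNJ2 in the closing part. Regroupings of the wells were limited to 21 per test, the real one included. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and scran 1.30.0 were used.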

Results

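The series measured RNA in 96 wells of 1 plate with 8 rows and 12 columns, 1 human embryonic stem cell per well as the labels describe it. The cells were of HUES64, an established embryonic stem cell line, here carrying an inducible knockout of DNMT1, the enzyme that restores DNA methylation after replication. The RNA part of each well was read by SMART-seq2, a full-length method for single cells, and the methylation part was not analysed here. All 96 libraries carried the same labels at day 0, so there was 1 group and no comparison between conditions. The labels disagreed on doxycycline: the description of every library gave it as added, and the induction field of every library gave it as not added. No label named a second culture, so the group counts as 1 sample, and the SDs, intervals and p-values below describe the wells of this plate only. The files held reads without molecular identifiers, and floors and intervals on shares of reads therefore cover counting error alone. The other intervals cover the spread over libraries or, where named, over genes.

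Of all reads recorded, 11.2% were assigned to genes. The libraries had a median of 6994040 reads, from 5937 to 12933539. Reads assigned to genes had a median of 660168 per library (SD 452337, n = 96), from 768 to 1877837. In the median library 38.4% of the reads were unmapped, 31.3% mapped to more than 1 place, 15.9% fell outside genes and 11.3% were on genes. The forward-strand column held 49.6% of the stranded gene reads in the median library, so the counts did not separate a gene from its antisense partner. At least 100000 gene reads and 2000 genes were found in 90 libraries, which are called passing here, and 6 libraries fell short. In the passing libraries, with 105528 to 1877837 gene reads, the floor of 3 reads corresponded to 28.4 down to 1.60 CPM, the gene's reads scaled to a common total of gene reads.

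How much of the transcriptome a single cell showed was the first technical question. Lactate dehydrogenase B (LDHB), the elongation factor EEF1A1, the nucleolar protein NPM1 and the ribosomal protein RPLP0 led after 5 loci described below, among genes not encoded in mitochondria. LDHB had 3096 ± 1662 CPM (SD, n = 90) and EEF1A1 had 2853 ± 1630 CPM. NPM1 had 2688 ± 1371 CPM and RPLP0 had 2487 ± 1290 CPM. Mitochondrially encoded genes took a median of 9.38% of the gene reads, led by MT-CO1 with 23529 ± 17634 CPM and MT-RNR2 with 16832 ± 10262 CPM. A passing library showed a median of 13930.5 genes with a read (SD 2527, from 7986 to 19336), and 7715 after thinning to 100000 gene reads (SD 2106, from 3086 to 14850). The 14850 belonged to well G3 and the next highest, 14427, to well F9. Their mitochondrial shares were 0.00778% and 0.00959%, so a high count of genes need not mean more RNA of the cell. Libraries differed in which genes they showed: 10 pooled cells gave 31492 ± 1258 genes (SD over 100 draws), all 90 gave 47423, and 599 genes had a read in every passing library. These counts do not separate differences between cells from sampling or background reads. Spearman's rho between pairs of cells across 26843 genes had a median of 0.452 (SD 0.103, from 0.179 to 0.691, 4005 pairs). Genes are not independent replicates, so no p-value goes with it.

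The 5 loci with the highest mean level apart from mitochondrial genes were KCNJ2, PDE4A, DGCR14, RP11-217O12.1 and FLG-AS1. KCNJ2, which encodes a potassium channel and lies on chromosome 17 from 70168673 to 70180048 (GRCh38), had 19577 ± 30463 CPM (SD, n = 90). It was the gene with the most reads in 19 passing libraries. In 9 libraries the mitochondrial share was below 1%, and 6 of these passed. There KCNJ2 took a median of 14.4% of the gene reads (from 0.959 to 17.6), against 0.954% in the other 84 passing libraries. The median was 15.3% in the 7 of these 9 in rows A to E and H, and 1.06% in the 2 in rows F and G. The 5 loci together took a median of 24% and 2.02%. The reads of those 9 libraries, pooled, serve below as a level to compare with. It was chosen after the values were seen. It is not the level that such reads would give in the other libraries, where the 5 loci took a smaller share. A mean below it therefore does not place a gene at or under background. Means over the 90 passing libraries also include 6 of these 9.

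**Figure D1:**
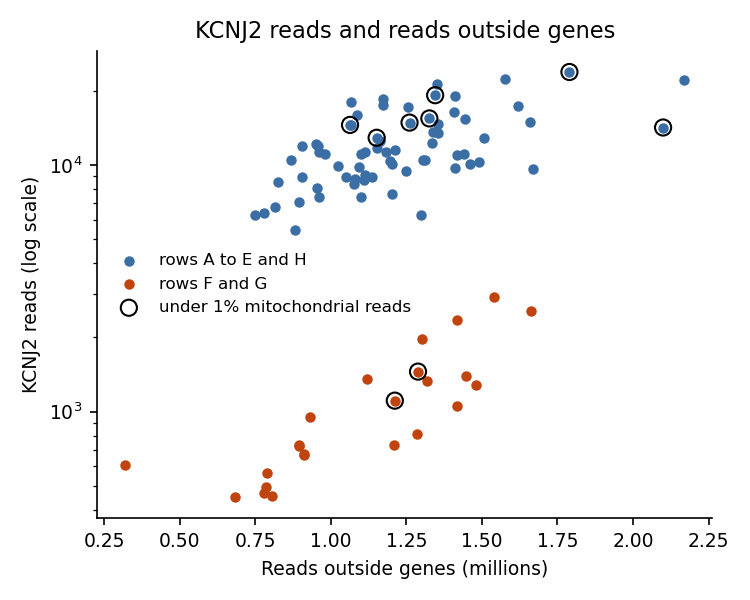
Reads on KCNJ2 (log scale) against reads outside genes for each library with more than 10000 gene reads; colours give the plate rows, and rings mark the 9 libraries with under 1% mitochondrial reads. The libraries of rows F and G lie apart, with fewer KCNJ2 reads at a like number of reads outside genes.

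Whether the cells carried the transcripts of their cell type was asked with 18 gene lists of 205 members, fixed before the data were examined. Core pluripotency genes were abundant: TDGF1, a co-receptor of NODAL signalling, had 639 ± 459 CPM (SD, n = 90), DPPA4 had 537 ± 334, L1TD1 had 521 ± 356, and POU5F1, a central pluripotency factor, had 419 ± 323. GDF3, a growth factor of the same list, averaged 644 ± 765. Of the 18 pluripotency members 15 had a mean of at least 10 CPM. In 12 of the 18 the mean over the 84 passing libraries with at least 1% mitochondrial reads was more than 5 times the level in the pool of those below 1%. NANOG was lower at 54.4 ± 56.8 CPM, SOX2 at 31.3 ± 45.7 and ZFP42, a gene of the same list, at 3.01 ± 22.3, with a median of 0 and 211 CPM in 1 library. All 8 primed members reached 10 CPM, led by CD24 with 428 ± 337 and PTPRZ1 with 232 ± 235. Of the 9 naive members only TFAP2C did, with 13.6 ± 35.8 CPM, and KLF17, DPPA3 and DPPA5 stayed at 2.14, 1.46 and 6.80 CPM; a single library at 113 CPM set the mean of DPPA3 and 1 at 274 much of that of DPPA5. Each of the 205 members had a read in some passing library.

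Genes of the cell cycle and of glycolysis were also high. All 22 G2/M members had means of at least 10 CPM, among them TOP2A with 647 ± 545, UBE2C with 466 ± 500 and CDK1 with 396 ± 417. Of the 20 G1/S members 18 did, led by PCNA with 314 ± 536 and MCM6 with 149 ± 360. PGK1, ENO1 and LDHA of glycolysis had 1093 ± 1133, 968 ± 638 and 872 ± 834 CPM. Housekeeping genes included PPIA with 1320 ± 836, ACTB with 1375 ± 685 and GAPDH with 1047 ± 876 CPM. Of 10 p53 targets 8 reached 10 CPM, led by ZMAT3 with 63.7 ± 123 and MDM2 with 58.1 ± 86.7. Of 11 immediate early and heat shock genes 3 did, with EGR1 at 18.9 ± 135 and FOS at 15.7 ± 52. A single library held 75.5% of all EGR1 CPM, and without it the mean was 4.68. Members of these lists were not all above the comparison level: CCNB2 averaged 874 CPM against 3152 in the pooled libraries with under 1% mitochondrial reads, and CCNA2 averaged 305 against 1087. This alone does not place either gene at the level of background reads.

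DNMT1, the gene the line allows to be deleted, lies on chromosome 19 from 10133345 to 10231286 (GRCh38). It had a mean of 29 ± 45.6 CPM (SD, n = 90) and a median of 6.0. A read was present in 80 of 90 passing libraries, or 88.9% (95% exact binomial interval 80.5 to 94.5), and 37 reached 10 CPM. The pooled libraries with under 1% mitochondrial reads held DNMT1 at 24.8 CPM. With no control group and no statement of which exons the deletion removes, the level says nothing of whether the gene was intact. Its partner UHRF1 averaged 15.4 ± 17.7 CPM against 20.8 in that pool. The methyltransferase DNMT3B had 195 ± 188 CPM against 19.8, the remodeller HELLS 241 ± 183 against 9.91, and the demethylating enzyme TET1 161 ± 190 against 4.95. DNMT3A went the other way, with 118 ± 86.1 CPM against 251. Germline genes whose promoters are normally methylated had low levels: none of the 15 reached a mean of 10 CPM, and the highest, GTSF1, had 4.17 ± 23.1, with a median of 0 and 202 CPM in 1 library. Of 17 imprinted genes 8 reached 10 CPM, led by MEST with 268 ± 222, SGCE with 69.7 ± 109 and KCNQ1OT1 with 64.5 ± 116, the last of these against 92.1 in the pool.

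**Figure D2:**
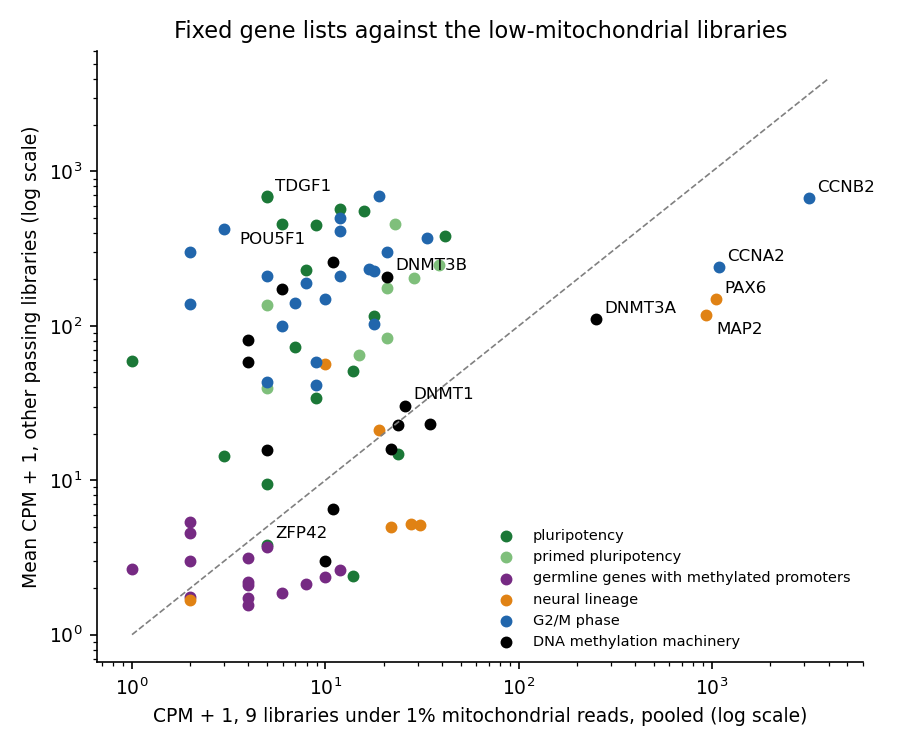
Mean CPM + 1 in the 84 passing libraries with at least 1% mitochondrial reads against CPM + 1 in the 9 libraries below 1%, pooled (both log scales), for members of 6 fixed lists. The dashed line marks equal levels; DNMT3A, PAX6, MAP2, CCNA2 and CCNB2 are among the members below it.

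Cells with another lineage programme were sought as passing libraries with at least 3 markers of a lineage at 10 CPM. Such a programme was counted in 72 of 90 libraries, or 80% (exact interval 70.2 to 87.7). In the shallowest libraries 10 CPM lay below the floor of 3 reads, as in wells F3 (25.3 CPM) and E10 (15.3 CPM). A marker there could rest on fewer than 3 reads, and both of these libraries met the endoderm criterion. The neural list alone gave 71, the primitive streak list 13, trophoblast and amnion 12, endoderm 7, fibroblast 5 and mesoderm 2. Without the 6 passing libraries under 1% mitochondrial reads these counts were 65, 12, 7, 3, 2 and 1 in the same order, and 8 of the 12 trophoblast and amnion libraries lay in rows F and G. The neural markers with the highest means were PAX6, with 223 ± 350 CPM, and MAP2, with 171 ± 236, which were at 1044 and 927 CPM in the pooled libraries with under 1% mitochondrial reads. PAX6 reached 10 CPM in 87 of the 90 libraries and MAP2 in 90, so the count turned on a further marker. NES reached 10 CPM in 57 libraries and TUBB3 in 34. In the other lineage lists KDR, a receptor for vascular growth factor, had 140 ± 208 CPM against 9.91 in that pool, MIXL1 of the primitive streak list 34.6 ± 59.4 against 19.8, and CER1 of the endoderm list 20 ± 80.1 against 7.92. A single library held 35.8% of all CER1 CPM, and the mean rested in part on it. GATA3 of the trophoblast and amnion list had 31.5 ± 59.2 against 153, and COL1A2 of the fibroblast list 39.6 ± 105 against 9.91. SOX1, another neural factor, was low at 5.81 ± 8.87 CPM. All 6 passing libraries with under 1% mitochondrial reads met the neural criterion. The count thus does not separate cells of another type from reads that those libraries share.

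Variability between cells was described against a trend of the squared coefficient of variation (CV2) on the mean. Of 9262 genes 1278 lay at least 1 above the trend in log2 CV2, which is 13.8%. The largest excesses were those of fibronectin FN1 (5.44), LXN (5.41), LMBRD1 (5.04), MED14 (5.03) and ACRC (4.69). PHF11, TERF1P2, RP11-300M24.1, PRICKLE2, KCNJ2, LMO7, SHISA2, PITPNC1, ERGIC2, ACYP1, GOLGA5, ATP5F1, FAM3C, RP11-121A8.1, RPL7P52, TSLP, CC2D2A, JAZF1, GSDMD and LINC00871 followed, with 3.76 for the last of these 25. Single libraries made these values: in 23 of the 25 genes at least 50% of all CPM came from 1 library. The library of well F3 was the highest for 12 of them and that of well F2 for 4. GAPDH was at 16.9 CPM in F3 and 2.77 in F2, and both had more MT-CO2 than MT-CO1 (log2 ratio 2.63 and 0.373). Such excesses therefore do not separate differences between cells from the quality of the libraries. With each gene's highest library left out, 599 genes lay past the threshold, 487 of them among the 1278. Of the 25, 11 could still be tested, and among these FN1 and KCNJ2 lay past it. Of the fixed lists 16 members lay past the threshold: GDF3, TET3, PAX6, TBXT, CER1, COL1A2, MCM2, MCM6, PCNA, CDC6, CCNB2, SESN1, FOS, EGR1, DUSP1 and PGK1. Without each gene's highest library COL1A2, MCM2, MCM6, PCNA and CDC6 fell below the threshold, and EGR1 and DUSP1 had too low a mean to be tested.

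**Figure D3:**
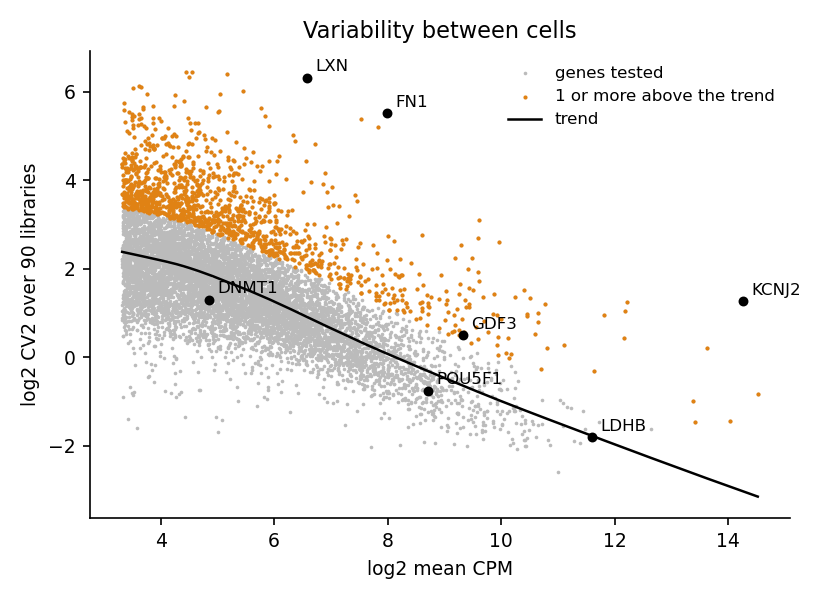
log2 CV2 over the 90 passing libraries against log2 mean CPM for the 9262 genes tested; orange points lie at least 1 above the black trend line, and black points are labelled genes. POU5F1 and DNMT1 lie below the trend, and KCNJ2, FN1 and LXN far above it.

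Among the fixed lists, pluripotency genes varied less than random lists of the same mean level, with a median excess at the 2.28 percentile of 10000 lists. The DNA methylation genes lay at the 1.28 percentile. Both left the lowest 5% when variability was measured as scran's biological component (91.5 and 16.3 percentiles) and when rows F and G were left out (8.03 and 7.0). Members of 5 lists rose and fell together from cell to cell more than random lists did. The median rho between members was 0.513 for glycolysis, 0.376 for housekeeping and 0.317 for G2/M genes, each above all 10000 random lists. It was 0.231 for pluripotency (99.7 percentile) and 0.211 for G1/S genes (99.6 percentile). With ranks residualised on depth and genes detected the median rho fell to 0.193 for housekeeping and 0.121 for pluripotency genes, still above the 95 percentile. Over 84 libraries the median rho of members with the log2 ratio of MT-CO2 to MT-CO1 was -0.469 for glycolysis and -0.432 for housekeeping genes, and from -0.258 to -0.205 for the other 6 lists with values, those that did not co-vary included. DNA methylation genes, at 0.0837, and imprinted genes, at 0.0580, did not co-vary more than random lists.

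Relations across cells were computed for a family of 15 pairs of measures over the 90 passing libraries, with two-sided permutation tests of 100000 resamples and Benjamini-Hochberg adjustment. The pluripotency and primed scores moved together (r = 0.82, adjusted p = 5e-05, from the smallest p the permutations can give; rho = 0.72; r = 0.80 without the 2 libraries farthest out). So did the G1/S and G2/M scores (r = 0.45, adjusted p = 5e-05; rho = 0.46; 0.44 without 2). In rows A to E and H both cycle scores also rose with genes detected at 100000 reads, as given below. No relation between scores was computed with genes detected held constant, so scores may move together through the quality of the libraries. DNMT1 was higher in cells with a higher G1/S score (r = 0.37, p = 0.00034, adjusted p = 0.00114; rho = 0.37; 0.42 without 2). The p53 target score rose with the G2/M score (r = 0.34, p = 0.0009, adjusted p = 0.00225; rho = 0.35; 0.36 without 2). DNMT1 and UHRF1 showed no relation (r = 0.01, p = 0.943; rho = -0.01). In all, 11 of the 15 relations passed the adjusted threshold of 0.05. Within the 62 passing libraries of rows A to E and H and the 22 of rows F and G, each with at least 1% mitochondrial reads, 7 of the 11 kept their sign in both sets. Within those sets the pluripotency and primed scores had r = 0.78 and 0.78, the cycle scores 0.41 and 0.33, DNMT1 and the G1/S score 0.40 and 0.47, and the p53 and G2/M scores 0.29 and 0.54. Among these only the pluripotency and primed scores passed the adjusted threshold in rows F and G. DNMT1 with the G1/S score was not called on residuals after plate row and column means (r = 0.21, adjusted p = 0.0809) or after thinning (r = 0.19, adjusted p = 0.108), and neither was the p53 score with the G2/M score (r = 0.23, adjusted p = 0.0546, and r = 0.21, adjusted p = 0.0697). Over all alternatives the adjusted p ran from 0.000487 to 0.157 for the former and from 0.0015 to 0.284 for the latter.

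DNMT1 rose with DNMT3B over all cells (r = 0.24, p = 0.0219, adjusted p = 0.0298; rho = 0.25, adjusted p = 0.0337; 0.25 without 2), with r = 0.38 in rows A to E and H and -0.24 in rows F and G. DNMT1 and the G2/M score had r = 0.25 (p = 0.0179, adjusted p = 0.0269; rho = 0.23, adjusted p = 0.0434; 0.26 without 2), with 0.32 and 0.24 in these sets. The pluripotency score fell as the lineage score rose (r = -0.37, p = 0.00038, adjusted p = 0.00114; rho = -0.24, adjusted p = 0.0407; -0.36 without 2), with -0.14 and -0.52 in the sets. Without the 6 passing libraries under 1% mitochondrial reads it was not called (r = -0.20, adjusted p = 0.0852; rho = -0.12), nor under the stricter quality filter (r = -0.13, adjusted p = 0.334, the range over alternatives being 3.75e-05 to 0.366). The G1/S score rose with genes detected at 100000 reads (r = 0.25, p = 0.016, adjusted p = 0.0266; 0.18 without 2), with 0.68 and 0.21 in the sets, and its rho of 0.21 did not pass (adjusted p = 0.0652). Gene reads and genes detected at 100000 reads had r = -0.50 (adjusted p = 5e-05; rho = -0.34, adjusted p = 0.0042; -0.46 without 2), with 0.10 and -0.40 in the sets. The mitochondrial share and genes detected at 100000 reads had r = -0.29 (p = 0.00704, adjusted p = 0.0151; rho = -0.26, adjusted p = 0.0313; -0.49 without 2), with -0.08 and 0.23 in the sets, and it was not called without libraries under 1% mitochondrial reads (r = -0.05, adjusted p = 0.728, the range over alternatives being 0.00048 to 0.728). The immediate early score and the mitochondrial share had r = -0.28 (p = 0.00913, adjusted p = 0.0171; -0.19 without 2), with -0.10 and 0.43 in the sets, and a rho of -0.22 that did not pass (adjusted p = 0.059). The remaining relations, of gene reads with genes detected (r = 0.15, adjusted p = 0.202), the G2/M score with genes detected at 100000 reads (r = 0.09, adjusted p = 0.438) and the glycolysis score with the mitochondrial share (r = -0.03, adjusted p = 0.823), were not called over all passing libraries. In rows A to E and H with at least 1% mitochondrial reads all of these passed (r = 0.50, adjusted p = 0.00015; r = 0.59, adjusted p = 5e-05; r = -0.37, adjusted p = 0.00966), and in rows F and G they did not (0.50, -0.03 and -0.06). After thinning and on residuals after plate row and column means, DNMT1 with DNMT3B, DNMT1 with the G2/M score, the G1/S score with genes detected at 100000 reads and the immediate early score with the mitochondrial share were not called.

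The last comparison asked whether the position on the plate moved the measures. The libraries of rows F and G differed from those of the other 6 rows in what they held. Their unmapped share had a median of 21.3% (from 16.3 to 26.3, n = 24), against 40.1% (from 29.5 to 46.9, n = 72). Their reads outside genes were at 33.4% against 15.2%, and their total reads at 3617690 against 7558200. At 100000 gene reads they showed a median of 9071.5 genes, against 7378 in 66 passing libraries of the other rows. Plate row accounted for 91.8% of the variance of the share outside genes and 43.9% of that of genes detected at 100000 reads (permutation p = 1e-05, the smallest the permutations can give; adjusted p = 6e-05 over 12 tests). Edge wells had a lower share outside genes than interior wells (medians 15.2% and 17%, adjusted p = 0.0305), and this did not pass without rows F and G (adjusted p = 0.268) or without libraries under 1% mitochondrial reads (adjusted p = 0.0611). Without those rows plate row still accounted for 29.8% of the variance of genes detected at 100000 reads (adjusted p = 0.00804) and 22.7% of that of the share outside genes (adjusted p = 0.0386). Gene reads passed for no position over all libraries. They passed for plate column without rows F and G (adjusted p = 0.0386), and without libraries under 1% mitochondrial reads for plate row (adjusted p = 0.0247) and edge against interior wells (medians 1049380 and 617954, adjusted p = 0.00392). Plate column passed for none of the other 3 measures in any setting.

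**Figure D4:**
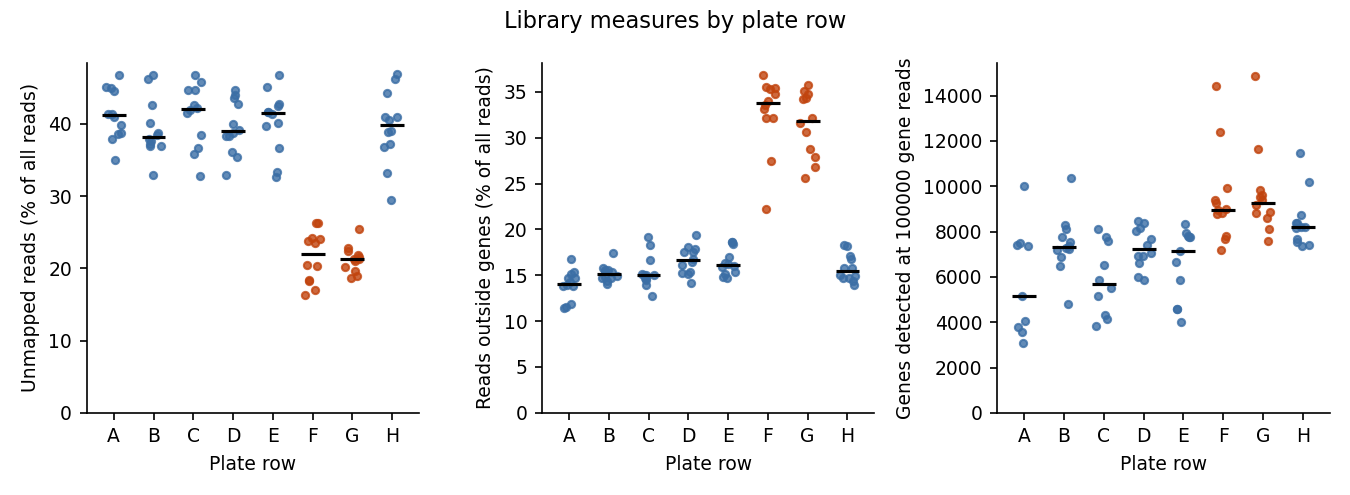
Unmapped reads and reads outside genes (percent of all reads, 96 libraries) and genes detected at 100000 gene reads (90 passing libraries) by plate row; each point is a library, and bars give row medians. Rows F and G, in orange, lie apart in the first 2 panels.

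For single genes, edgeR's quasi-likelihood test called 2831 of 12356 genes by plate row (Benjamini-Hochberg adjusted p under 0.05), with plate column in the model. Of these, 2112 also differed between rows F and G and the rest, 1503 higher and 609 lower in rows F and G. Without those rows 13 genes of 11620 were called. Of 149 tested list members 21 were called, and 23 when adjusted over the list alone. TFAP2A (log2 difference 2.71), GATA3 (2.10), MEG3 (1.74), PAX6 (1.62) and CCNB2 (1.25), chosen after their values were seen, were higher in rows F and G, and PDGFRA (-1.94) was lower. In the pool of libraries under 1% mitochondrial reads GATA3, PAX6 and CCNB2 stood at 153, 1044 and 3152 CPM. Not all genes high in that pool were higher in rows F and G. CCNA2, also high there, had a log2 difference of -1.28 (edgeR, adjusted p = 0.00279). MAP2, likewise high there, had 0.166 (adjusted p = 0.708). No G1/S or glycolysis member was called. Plate column gave 594 genes by edgeR, 547 by DESeq2 and 0 by limma-trend, which had 1046 at an unadjusted p under 0.05.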

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

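The tests of KCNJ2, of a separate batch and of a gradient across the plate were chosen only after the result was seen, and those of depth and of regrouped wells before.

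Outside the counts of the passing libraries 2 values are given for a closer look, because reads were present in data set aside; with no control samples they were compared with a count of 0 alone, which any such reads exceed. Reads mapped to more than 1 place, which no comparison used, made up a median of 31.3% of all reads over the 96 libraries. In the 6 libraries that did not pass, KCNJ2 held 15.6% of the pooled gene reads, 44150 of 283258 (exact interval 15.5 to 15.7). The 3 of these with more than 10000 gene reads also entered the pool of libraries with under 1% mitochondrial reads and the relations of KCNJ2.

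In rows A to E and H, KCNJ2 and 4 other loci led the libraries with few mitochondrial reads, while in the 2 such libraries of rows F and G KCNJ2 held a median of 1.06% of the gene reads, less than RP11-217O12.1 (3.07%), FLG-AS1 (2.35%) and PDE4A (1.59%). Expression of KCNJ2 in the cells was argued against: over 69 libraries of rows A to E and H its reads fell as reads on other genes rose (rho = -0.441, bootstrap interval -0.613 to -0.231; r = -0.45, adjusted p = 0.000251 over 16 relations; -0.43 without the 2 libraries farthest out), with a rho of -0.457 (adjusted p = 0.0414) over 24 libraries of rows F and G, where r did not pass (-0.32, adjusted p = 0.209; -0.26 without 2). The 69 libraries include those with few mitochondrial reads in which the pattern was seen, so this result in part restates it. KCNJ2 reads rose with reads outside genes (rho = 0.532, interval 0.332 to 0.705; r = 0.58, adjusted p = 2.67e-05; 0.52 without 2), with a rho of 0.895 in rows F and G. A candidate explanation is reads that do not come from poly(A) RNA of the cell, such as genomic DNA or primer products, which these counts do not separate. No other biological explanation was tested, since all wells carried the same labels.

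Rows F and G stood apart from the other 6 rows. They still showed a median of 1693.5 more genes at 100000 gene reads (interval 1260 to 2215). This argued against a lower sequencing depth as the whole cause. A gradient in the unmapped share was argued against too. Row H beside them had a median of 39.9%, inside the 38.2 to 42% of rows A to E. Other measures are not covered by this. Without rows F and G, plate row still accounted for 29.8% of the variance of genes detected at 100000 reads (permutation test, adjusted p = 0.00804). Whether that measure followed a gradient was not tested. A separate sequencing or library batch stays open, and the labels name none. KCNJ2 reads per 1000 reads outside genes had a median of 0.842 in rows F and G and 9.72 in the others, and 0 of 69 libraries of the others were as low as the highest of rows F and G, but any cause that sets these rows apart would give such a value.

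For single genes, chance could be excluded for plate row over all rows together. Only 1 of 21 regroupings of the wells, the real one, gave as many genes (2831, against 27 in the highest other). With 21 regroupings, 1 of 21 is the smallest share possible. Without rows F and G the real rows gave 13 genes by edgeR and 1 by limma-trend. The wells were not regrouped without rows F and G, so chance was not excluded among the other rows. Chance could not be excluded for plate column, where 2 of 21 gave as many (594, against 730 in the highest other). The other column regroupings called a median of 464 genes by edgeR, for which the cause was not tested. For the real columns limma-trend called 0, with 1046 at an unadjusted p under 0.05.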

How the results depend on the processing

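Leaving out rows F and G, libraries under 1% mitochondrial reads, the library of well F3 or each gene's highest library, splitting the rows, exchanging columns 1 and 12 and edgeR's default dispersion were chosen only after the data were seen. Of 821 values under alternatives 728 were labelled unchanged. Counts had to stay within a set fold of the main count, and levels and medians within 1 SD. Tested values and list percentiles had to stay on the same side of the threshold. Sign was compared only for relations called in some setting. Unchanged were 45 of 45 values for list co-variation, 29 of 36 for list variability and 43 of 48 for plate measures. So were 103 of 165 for relations and 76 of 95 for the main counts and medians. The 432 gene levels moved by less than 1 SD, which says little, since most SDs are near or above the mean. Of the other relations 47 were no longer called, 9 were newly called and 6 reversed. Genes detected were 6213 at 5 reads and 7715 after thinning, lower by construction. The correlation was 0.545 as Pearson's r of log2(CPM + 1) and 0.574 as Pearson's r of log2(CPM + 10). Variable genes numbered 3637 and 423 with mean minimums of 1 and 50 CPM, which change the genes tested, and 599 without each gene's highest library. Lists outside the 5 to 95 percentile range of variability, 2 in the report and both low, numbered 3 with scran size factors, where the housekeeping list joined them (3.06 percentile), 1 with scran's modelGeneVar and 1 without rows F and G. In the last 2 settings this was the G2/M list on the high side (95.9 and 96.1), and no list was low. With modelGeneVar the pluripotency list reversed to the 91.5 percentile. Against 11 relations called, the number was 7 with scran size factors, 6 after thinning, 6 on residuals after row and column means, 2 in columns 7 to 12 and 1 in rows F and G with at least 1% mitochondrial reads. The 6 in both of those settings include gene reads with genes detected, which was not among the 11, and the last 2 settings hold fewer libraries. Reversed relations were gene reads with genes detected (-0.497 after thinning, by construction), gene reads with genes at 100000 reads (0.101 in rows A to E and H), and in rows F and G the mitochondrial share with genes at 100000 reads (0.230), DNMT1 with DNMT3B (-0.239) and the immediate early score with the mitochondrial share (0.434, and 0.00614 without libraries under 1% mitochondrial reads). Genes by row numbered 13 by edgeR and 1 by limma-trend without rows F and G (unadjusted 1590 and 1057). Genes by column numbered 1555 with edgeR's default dispersion and 0 by limma-trend, also 0 without libraries under 1% mitochondrial reads and 0 without rows F and G (unadjusted 1046, 1189 and 1087). Where no construction is named the cause was not tested. Exchanging columns 1 and 12 cannot change these tests. Depth limits single genes: 3 reads are 28.4 CPM in the shallowest passing library.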

Other observations

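The library of well D4 and the comparison of MT-CO2 with MT-CO1 were singled out, and the tests of transcript length and GC content chosen, only after the result was seen; the test of background reads was chosen before.

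The library of well D4, with 506450 gene reads, lacked most pluripotency transcripts. POU5F1, NANOG, SOX2 and DPPA4 had 0 reads there, and TDGF1 had 1.97 CPM. LIN28A, an RNA-binding protein of the same list, had 63.2 CPM. Of 18 pluripotency members 2 reached 10 CPM, the lowest of the 84 passing libraries with at least 1% mitochondrial reads, whose median was 12. Wells C12 and F3 had 3 such members, and C4, E10, E4 and F10 had 5, so the count alone does not set D4 apart. FN1, which encodes fibronectin, had 16347 CPM (median of the other 83 libraries 15.5, highest 1176). SHISA2 had 2421 CPM (highest other 422) and APELA 1795 (highest other 413). The chemokine receptor CXCR4 had 426 CPM (highest other 90.3), the carrier protein TTR 877 (highest other 3.64) and the apolipoprotein APOA2 1593 (highest other 23.5). By the lineage lists, D4 met the trophoblast and amnion criterion with 3 markers and not the endoderm one, with 2. Of the housekeeping genes, GAPDH had 871 CPM (median of the others 1072) and ACTB 436 (median of the others 1449). In the other wells named here GAPDH was at 0 CPM in C12, 16.9 in F3, 3.84 in C4, 8.15 in E4, 240 in E10 and 198 in F10.

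MT-CO2 exceeded MT-CO1 in 19 of the 84 passing libraries with at least 1% mitochondrial reads, GAPDH was under 50 CPM in 12, and 11 showed both. GAPDH, picked because it was low there, had the most negative rho with the log2 ratio of 3354 genes above 50 CPM with an annotated length (-0.764, with -0.849 in rows A to E and H and -0.800 in rows F and G), so no p is given for it. ACTB showed no relation that passed (rho = -0.037, adjusted p = 0.740 over 16 relations), and genes detected at 100000 reads fell as the ratio rose (rho = -0.717; r = -0.77, adjusted p = 2.67e-05; -0.83 without 2), with rho of -0.850 in rows A to E and H and -0.548 in rows F and G, where r did not pass (-0.40, adjusted p = 0.114). For GC content the rho was -0.0634 across 3354 genes (interval -0.0977 to -0.0288), within the bound set against it, genes not being independent replicates. Loss of long complementary DNA stays open, as the rho with transcript length was -0.173 (-0.207 to -0.140), between the bounds set for and against it. Length and GC content were medians over all protein-coding transcripts annotated for a gene, which need not be the expressed ones. Neither the length test nor the GC test can therefore decide its explanation. Background reads stay open too. Their share of gene reads was estimated from the reads outside genes. The scale was 0.088 gene reads per read outside genes, the median of the libraries under 1% mitochondrial reads. The rho of this share with the ratio was 0.0824 over the 84 libraries (-0.115 to 0.284). Rows F and G, which held a larger share of reads outside genes, were pooled with the others, so this value cannot decide. No biological explanation was tested.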
